A study of Rattus norvegicus with 36 samples.

How the data were processed

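The labels describe total RNA from frozen hippocampus of 36 female rats in 6 groups. The submitters' processing notes name kallisto 0.43 and DESeq2 without saying which step each was used for. The reference transcriptome is not given in the sources used here. The deposited table has 36 columns of per-sample values, which were not used in any result, because their names could not be tied to samples. What its rows hold, and on which scale, was not examined. Only the column names were compared with the samples' labels, ignoring case and punctuation. The comparisons between groups, with their tests and gene lists, had been fixed before the data were examined and were not run.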

Results

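Hippocampal RNA of female rats was sequenced in 36 libraries, which the labels divide into 6 groups of 6 libraries each. Regularly cycling animals were sampled at 6 months and at 9 months of age. Animals with irregular cycles and animals that had stopped cycling were also sampled at 9 months. A separate group of acyclic animals was sampled at 16 months. The remaining group, RegOVX10m, carries the same Reg prefix in its label as the regular cyclers. Its animals had their ovaries removed at 9 months and were sampled at 10 months. The design implies comparisons of age among regular cyclers, of cycle status at 9 months and of age among acyclic animals. It also implies comparing the animals without ovaries with intact regular cyclers at 9 months. A further comparison is of surgical with natural loss of cycling, against acyclic animals at 9 months. In both comparisons with surgery, the animals without ovaries were sampled at 10 months, so age went with the surgery.

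None of these comparisons was made, and no gene expression value is reported. The deposited table holds 36 columns named by the tissue and a running number. Of these, 0 carried the title of a sample, and 0 held the name of a group. The order of the samples was not used in place of names. Sorting the samples by accession and sorting them by title gave different groups at 18 of the 36 positions.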

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

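The match of column names to samples was the only result, and the rule of comparing whole names with titles, like both alternatives to it, was chosen after seeing the column names. Searching for each column name anywhere in a sample's labels gave 0 columns, as did comparing whole names with titles. When the number in a column name was compared with the ending of each title, 6 columns fitted a single title, 9 fitted several titles and 21 fitted none. That rule gave no usable assignment, since nothing in the labels ties the numbers to the titles. Its counts were fixed by how the columns and the titles are numbered, so a single fit is no evidence of a match. Other settings for the expression comparisons were not run, because the comparisons were not made.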
